A study of Mus musculus with 4 samples.

How the data were processed

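CITE-seq, which reads gene transcripts and antibody tags from the same cells, was performed on mouse hearts in 2 libraries. Per the labels, each library pooled the hearts of 4 C57BL6J mice, given either an agonist antibody against CD40 or a rat IgG isotype antibody. Per the labels' protocols, hearts were perfused, freed of the atria, minced, digested for 20 min at 37 °C and passed through 40-µm strainers, and live cells were sorted before capture with the 10x Genomics Chromium 5′ chemistry. The sample titles and the labels' protocols name a gate on CD45 without DAPI, whereas the series description names DRAQ5 without DAPI. Which of these gates was used cannot be settled from the files.

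The deposited matrices hold raw UMI counts per feature and cell barcode, as whole numbers with no normalization, for 32285 mouse genes and 198 antibody tags, 9 of them control antibodies. Per the file headers the matrices come from Cell Ranger 6.0.1, while the submitters' processing notes list Cell Ranger 3 and Seurat 3, and name the builds mm10 and GRCh38 without stating their roles. Every gene in the files has a mouse Ensembl ID. The barcodes had been selected before deposit; the caller's setting is not stated in the files, and no deposited file holds Seurat output, cell types or filters. Gene symbols and IDs are those of the deposited feature lists. Genome positions were not used here.

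Cells with at least 200 genes and under 10% mitochondrial UMIs were kept. These were 2558 of 4908 barcodes (52.1%) in the isotype library and 4278 of 7087 (60.4%) in the anti-CD40 library, and all other barcodes had 10% or more mitochondrial UMIs. Scrublet marked 5 isotype cells (0.195%) and 0 anti-CD40 cells, too few to be of use, so no cell was removed by it. Clusters with leading markers of different, unrelated classes were kept apart as mixed instead. The kept cells of both libraries were clustered together without integration: counts were scaled to 10000 UMIs and log transformed, 2000 variable genes were taken, and 30 principal components, 15 neighbours and a Leiden resolution of 1.0 were used (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9). Left out of the variable genes were 228 genes from 9 response lists (interferon, antigen presentation, CD40 signalling, chemokine, cytokine, cell cycle and dissociation genes), along with sex-linked, mitochondrial, ribosomal, haemoglobin and antigen receptor segment genes, so that cluster sizes do not rest on them. Genes outside these lists stayed eligible. Among them were Gbp2b, Cfb and Ly6i, leading genes of phagocyte-like clusters 0 and 1, so cluster sizes can still follow the response.

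Clusters were named from 19 marker lists and subclusters (Leiden resolution 0.8) from 8, with at least 3 leading markers required. Of 23 clusters, 16 were named in 9 classes, 4 were mixed and 3 stayed unnamed. The way markers were scored was set after the output was seen: markers shared by B cells and plasmacytoid dendritic cells were not counted against either, and a subcluster took a name only with more of its markers among its top 10 genes than any rival. Mature dendritic cell-like cells were not recovered at Leiden resolutions of 0.5 and 2.0 or with 15 components.

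Each group is 1 library, so no test, p-value or standard error across conditions was possible, and cells were not treated as replicates. The markers, gene lists, rule for named genes, minimums, handling of doublets and 28 of the alternatives were fixed before the data were examined. Shares of cells carry exact Clopper-Pearson 95% intervals. Summed UMIs per class and library were expressed as CPM (UMIs scaled to the class total) with exact Poisson intervals, and the ratio of anti-CD40 to isotype with an exact conditional binomial interval (scipy 1.17.1). Log2 ratios used a prior of 10 CPM. All intervals cover counting error only, not variation between mice or preparations. A gene at 0 UMIs in 1 library is given as at least N-fold higher or lower, computed with 3 counts in that library; a share of 0 that is compared is given with the limit that 3 cells would set and with its exact upper limit.

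Classes were compared with at least 50 cells in each library. Genes were named by a rule of size: the 15 highest and 10 lowest log2 ratios in mononuclear phagocyte-like cells, the 10 highest and 5 lowest in T cell-like cells, and the 5 highest and 3 lowest in every other class with at least 100 cells per library. They needed at least 30 UMIs and detection in 5% of the class in the library where the gene is higher. Markers of another class, mitochondrial, ribosomal, haemoglobin, receptor segment and sex-linked genes and unnamed gene models were passed over. Genes of the CD40, interleukin-12 and interferon-gamma axis were always named. Values of some genes and tags that these rules take are not reported here. The T cell-like class, with 39 isotype cells, is below the minimum for classes but has its own part of the rule, which sets no minimum.

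For 31 gene lists the median log2 ratio of members with at least 10 UMIs was set against 10000 random lists of the same size matched on expression in 20 bins. A list is described as standing apart above the 97.5th or under the 2.5th percentile of these. Members count as higher or lower by a 1.5-fold rule of size. Of the listed symbols, 5 were not in the annotation. Where a list held genes at 0 UMIs in 1 library and its median moved when these were set at their bound, both medians are given. Shares of cells with a transcript were computed after each cell was thinned to 1000 UMIs, leaving out shallower cells. Free RNA was estimated per class and library from C1qa, C1qb and C1qc, as the percent of the phagocyte-like level of these genes found in the class. This does not tell free RNA from a phagocyte captured in the same droplet. Where the expected level was subtracted, values below 0 were set to 0. A median of 0 or below after subtraction can come from this floor.

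Antibody tags were summed as UMIs per cell. Tags at least 3 times the highest control tag in the higher library were ranked by their share of the class's tag UMIs, and the 6 highest and 4 lowest are named, with lineage tags of other cells passed over; this tag rule, and the further tags given, were chosen after the values were seen. Tag values in all classes other than the phagocyte-like class were chosen in the same way.

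Of the alternatives, 28 were fixed in advance and 7 were chosen after seeing the data. They cover the cell filters, clustering settings, mixed clusters, prior, list minimum, thinning, cell weighting and 2 scalings (TMM from edgeR 4.0.16 and the median of ratios from DESeq2 1.42.0, R 4.3.3). The ratio and list computations were tested on simulated data with 200 changed genes of 12333, drawn at 10% of the library depth. For true log2 ratios of 1.58, -1.58, 1.0 and -1.0 the median recovered values were 1.39, -1.16, 0.83 and -0.73, drawn toward 0 by the prior. The intervals held the true ratio in 88%, 92%, 94% and 100% of 50 genes each, in 93.5% of all changed genes, and in 96.2% of unchanged genes. The pass mark for these intervals was limited to the pooled genes after the 88% had been seen. Of 200 simulated lists without a change, 4% fell outside the central 95%. The simulated genes varied independently, so this does not show how often real lists, whose genes can vary together, would fall outside it. Computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.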

Results

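Transcripts and surface proteins of single mouse heart cells were measured after treatment with an antibody that activates CD40, a receptor on B cells, dendritic cells and macrophages through which helper T cells deliver activating signals, or with an isotype control antibody. The isotype library held 4908 barcodes with 26847799 gene UMIs (median 1951 UMIs and 918 genes per barcode) and 18695756 tag UMIs. The anti-CD40 library held 7087 barcodes with 53736318 gene UMIs (median 3772 UMIs and 1476 genes) and 28053242 tag UMIs. After filtering, 2558 isotype cells (22687435 UMIs, median 5446 per cell) and 4278 anti-CD40 cells (47485251 UMIs, median 8284.5 per cell) remained. There were no replicates: each group was 1 library of 4 pooled hearts, differences between groups were not tested, and all intervals are exact 95% intervals for counting error only. Treatment cannot be told apart from anything else that differed between the preparations.

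The comparison of cell shares asked which cell types made up the sorted heart cells after CD40 activation, the subject the series description names. Mononuclear phagocyte-like cells, the macrophages and monocytes that clear debris and present antigen, made up a larger share of the anti-CD40 library. B cell-like cells, the antibody lineage, had a far lower share in it. T cell-like cells, which recognise presented antigen, had a larger share. Mature dendritic cell-like cells, which carry antigen to T cells, were found almost only in the anti-CD40 library when cells were named by cluster.

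Phagocyte-like cells were 839 of 2558 isotype cells (32.8%, 31.0 to 34.7) and 2344 of 4278 anti-CD40 cells (54.8%, 53.3 to 56.3), a difference of 21.99 percentage points. B cell-like cells were 395 (15.4%, 14.1 to 16.9) and 15 (0.351%, 0.196 to 0.578), a difference of -15.1 points. T cell-like cells were 39 (1.52%, 1.09 to 2.08) and 113 (2.64%, 2.18 to 3.17). Conventional dendritic cell-like cells were 88 (3.44%, 2.77 to 4.22) and 48 (1.12%, 0.828 to 1.48), and mature dendritic cell-like cells 2 (0.0782%) and 54 (1.26%, 0.9496 to 1.64). Natural killer (NK) cell-like cells, which kill infected or altered cells, were 5.24% (4.41 to 6.17) and 4.63% (4.02 to 5.30). Neutrophil-like cells, first responders to infection, were 6.53% (5.60 to 7.56) and 7.11% (6.35 to 7.92). Endothelial-like cells were 2.11% (1.59 to 2.75) and 2.92% (2.44 to 3.47), and fibroblast-like cells 1.92% and 1.57%. The sort before capture can set all of these shares, and its gate is stated differently in the protocols and the series description.

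Mixed clusters, kept out of these classes, held 17.2% of isotype and 10.7% of anti-CD40 cells, and unnamed clusters 13.8% and 12.9%. The mixed cluster of B cell and phagocyte markers held 338 isotype cells (13.2%) and 10 anti-CD40 cells (0.234%). The mixed cluster of T cell and phagocyte markers held 0 isotype cells, which allows up to 0.117% by 3 counts and 0.144% by the exact interval, and 233 anti-CD40 cells (5.45%, 4.79 to 6.17). Clusters mixing phagocyte and neutrophil markers held 3.95% and 5.00%. In 1 alternative each cell took the class with its largest marker share, each share divided by its mean over all kept cells. This works against abundant classes by construction, and it named 12.9% of isotype and 10.5% of anti-CD40 cells phagocyte-like. The phagocyte-like difference then turned to -2.39 points and that of conventional dendritic cells to 10.6 points, and mature dendritic cells were 3.32% and 8.93%. The conventional dendritic cell difference was 3.40 points at a Leiden resolution of 2.0 and 1.24 points with 15 components. The T cell-like difference, 1.12 points (0.103 to 2.08) in the classes above, was 2.99 to 6.56 points under 9 alternatives, and 1.25 points with an interval that includes 0 (-0.147 to 2.57) over named classes alone. That of B cells reached -28.1 points. Shares of B cells were 24.9% and 2.85% (122 anti-CD40 cells) at a Leiden resolution of 2.0 and 26.8% and 2.71% (116 cells) with response genes kept in the clustering. The NK cell-like difference, -0.610 points (-2.16 to 0.894), was -5.87 points (-7.90 to -3.91) with a filter of 500 genes and 5% mitochondrial UMIs and -3.05 points (-4.23 to -1.90) at a Leiden resolution of 2.0.

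**Figure D1:**
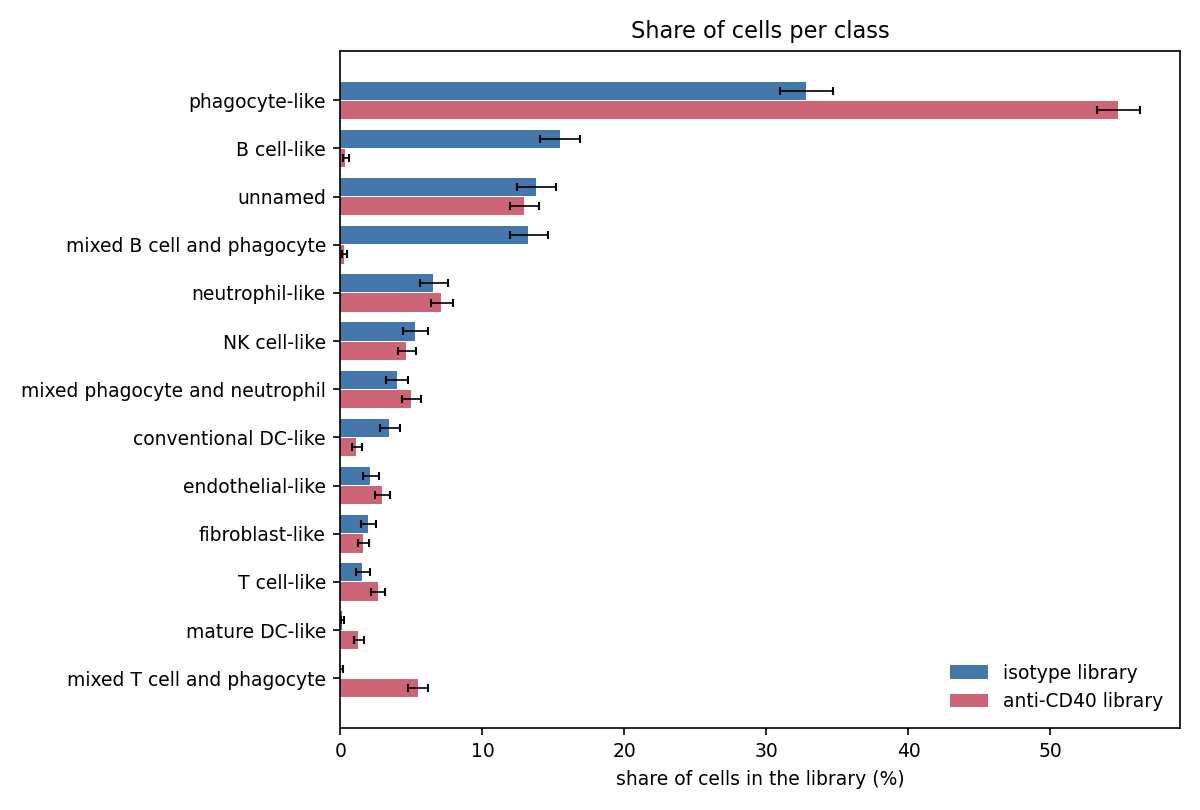
Share of all kept cells in each class (horizontal axis, percent) for the isotype and anti-CD40 libraries, with exact 95% intervals as error bars. Phagocyte-like cells took 32.8% and 54.8%, B cell-like cells 15.4% and 0.351%.

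The comparison within phagocyte-like cells asked which genes and surface proteins of heart macrophages and monocytes differ after CD40 activation. Cxcl9, a chemokine that draws activated T cells, Ly6a, the interferon-inducible protein Sca-1, and Iigp1, an interferon-inducible GTPase that acts against intracellular microbes, were far higher in the anti-CD40 library. Several guanylate-binding proteins, GTPases of the same defence, were higher with them. Genes of tissue-resident and alternatively activated macrophages were lower, among them Fcrls, Ccl24, an eosinophil attractant, and Retnla, a secreted product of alternatively activated macrophages. Cd40 itself was higher.

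Cxcl9 (ENSMUSG00000029417) was at 2.02 CPM (15 UMIs) in the isotype and 1493 CPM (45030 UMIs) in the anti-CD40 library, 737-fold higher (447 to 1317). Ly6a (ENSMUSG00000075602) was at 11.6 and 1743 CPM, 150.2-fold higher (121.6 to 187.8). Iigp1 (ENSMUSG00000054072) was at 7.15 and 1069.5 CPM, 149-fold higher (114 to 200). Gbp2b (ENSMUSG00000040264) was at 1.35 and 388 CPM, 288-fold higher (156 to 600). The other guanylate-binding genes named by size were Gbp6 (163-fold), Gbp8 (103-fold), Gbp4 (55.5-fold) and Gbp2 (34.3-fold). Cxcl13, which guides B cells into follicles, was 159-fold higher (77.3 to 397), at 0.945 and 151 CPM. Serpina3g, a protease inhibitor, was 103-fold, the monocyte chemokine Ccl8 41.7-fold and Cfb, complement factor B, 40.3-fold higher. The long noncoding RNA AW112010 was 38.4-fold, Ly6i 34.7-fold and Calhm6 25.8-fold higher.

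Fcrls (ENSMUSG00000015852) was at 264 and 14.1 CPM, 18.7-fold lower in the anti-CD40 library (16.8 to 20.8). Ccl24 (ENSMUSG00000004814) was at 106 and 2.06 CPM, 51.6-fold lower (39.8 to 68.0). Retnla (ENSMUSG00000061100) was at 348 and 27.8 CPM, 12.5-fold lower (11.6 to 13.6). Ltc4s, which makes leukotriene C4, was 12.3-fold lower and Hpgd, which breaks down prostaglandins, 9.98-fold lower. The organic anion transporter Slco2b1 was 8.003-fold, the growth factor Igf1 7.16-fold, and Gas6, which bridges dying cells to macrophages, 6.796-fold lower. The haemoglobin scavenger receptor Cd163 was 6.42-fold and fibronectin, Fn1, 6.04-fold lower.

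Of the CD40, interleukin-12 and interferon-gamma genes, Cd40 (ENSMUSG00000017652) was at 21.1 and 90.2 CPM, 4.29-fold higher (3.65 to 5.07). The chemokine gene Cxcl10 was at 112 and 801 CPM, 7.16-fold higher (6.68 to 7.69). Il12b (ENSMUSG00000004296), a subunit of interleukin-12, was sparse at 2 and 136 UMIs in 1 and 28 cells, 16.7-fold higher (4.54 to 139). This interval counts UMIs and does not cover the small number of cells that hold them. Il12a, the other subunit, had 14 and 3 UMIs, 19.0-fold lower (5.30 to 103); isotype B cell-like cells had it at 32.3 CPM. The receptor gene Il12rb1 was at 0.270 and 20.2 CPM, 74.7-fold higher (20.6 to 618), and Il12rb2 had 9 and 24 UMIs. Ifng had 5 and 58 UMIs, 2.85-fold higher (1.15 to 9.10). The interferon-gamma receptor gene Ifngr1 was at 352 and 192 CPM, 1.83-fold lower (1.75 to 1.92), and Ifngr2 at 132 and 124 CPM, slightly lower, but slightly higher under both scalings. Cd40lg had 0 and 1 UMIs.

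Different clusters held most of the class in each library: 616 of the 839 isotype cells were in cluster 2, whereas 940 and 895 of the 2344 anti-CD40 cells were in clusters 0 and 1. The median log2 ratio of all genes was -0.09 in the class, and scaling by TMM or the median of ratios raised log2 ratios by a median of 0.14 or 0.15, and those of abundant genes by more. Isotype phagocyte-like cells also carried more B cell products, with Ighd, an antibody chain gene, at 38.6 and 2.09 CPM. Leaving out phagocyte-like cells with 3 or more distinct lymphoid or neutrophil markers, chosen after seeing the data, removed 566 of 839 isotype and 1281 of 2344 anti-CD40 cells. It lowered the log2 ratio of Cxcl13 from 3.88 to 3.01 and moved that of Il12a from -0.24 to -0.06. That of Retnla, -3.24, was -3.94 with a filter of 500 genes and 5% mitochondrial UMIs and -2.27 with response genes kept in the clustering, and thinning raised that of Iigp1 from 5.98 to 6.58.

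**Figure D2:**
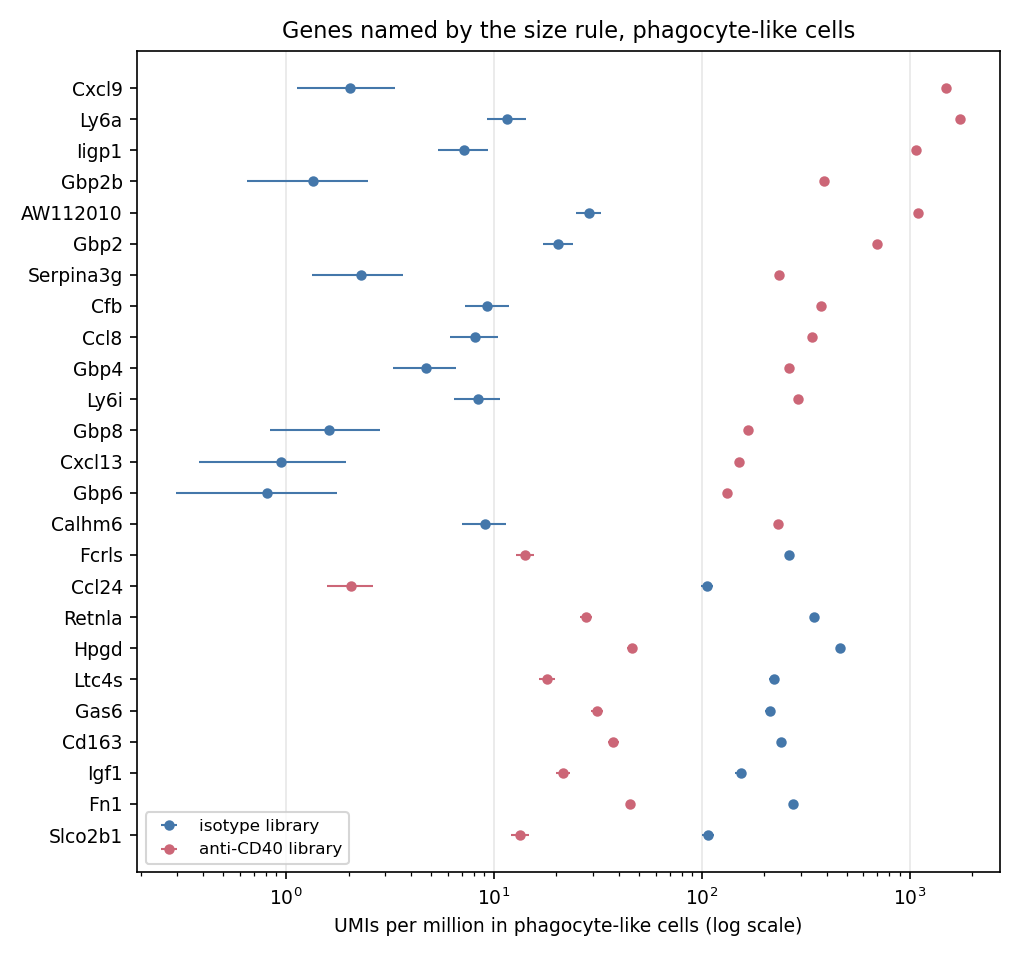
Class CPM (horizontal log axis) of the 25 genes named by size in phagocyte-like cells, as points for each library with exact 95% Poisson intervals. Cxcl9 sat at 2.02 and 1493 CPM, Ccl24 at 106 and 2.06 CPM.

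Among gene lists, the interferon-gamma response stood farthest apart, with all 37 measured genes over 1.5-fold higher in the anti-CD40 library and a median log2 ratio of 2.59. Type I interferon-stimulated genes had 28 of 30 higher (median 1.43), for example Zbp1, a sensor of viral nucleic acid (9.002-fold), and Ifit2 (10.9-fold). MHC class I presentation had 19 of 19 higher (median 1.46), among them the peptide transporter Tap1 (5.42-fold), H2-Q7 (6.74-fold) and H2-D1 (1.64-fold). MHC class II presentation had 9 of 13 higher (median 0.82), with the class II regulator Ciita 2.35-fold higher, and H2-Ob, a B cell-rich member, 4.02-fold lower. Glycolysis had 13 of 18 higher (median 0.98), such as Gapdh (2.39-fold) and Pgk1 (2.62-fold), while Hk2 was 1.61-fold lower. The other lists above the range of random lists had smaller medians. These were oxidative phosphorylation (0.36), cell cycle (0.25), the unfolded protein response (0.22), dendritic cell maturation (0.15), helper T polarisation (0.07, or 0.05 with genes at 0 set at their bound), inflammatory cytokines (0.07), the interleukin-12 and interferon-gamma axis (0.07) and lymphocyte effector genes (0.06). Within them, Cox5a of the respiratory chain was 2.35-fold, the proliferation gene Pclaf 2.24-fold and the NK receptor gene Klrk1 16.8-fold higher, while Cd83 was 2.74-fold and Il1b 2.25-fold lower.

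Resident macrophage genes were lower in 22 of 25 (median -1.64), with the platelet factor Pf4 4.83-fold lower and Timd4, a receptor for dying cells, 1.17-fold higher. Alternative activation and repair genes were lower in 16 of 20 (median -0.69). Fc receptors had 6 of 10 lower (median -0.61), with Fcgrt 2.76-fold lower but the activating receptors Fcgr4 6.87-fold and Fcgr1 2.47-fold higher. This list includes the B cell markers Fcer2a and Fcmr, and isotype phagocyte-like cells carried more B cell products. Its median thus does not describe phagocyte Fc receptors alone. Complement and efferocytosis genes had 9 of 21 lower (median -0.37), the scavenger receptor Stab1 4.12-fold lower and C3 8.04-fold higher. Iron handling had 6 of 13 lower (median -0.35), with the iron exporter Slc40a1 9.57-fold lower. Matrix genes had 13 of 22 lower (median -0.26), with Spp1 10.1-fold lower and Mmp14, a collagen-cleaving protease, 8.35-fold higher. The lysosome list had a median of -0.22, which TMM and the median of ratios moved to 0.01 and 0.02. Dissociation stress genes, an early response to tissue digestion, had 19 of 23 lower (median -1.21), such as Nr4a1 (5.73-fold) and Hspb1 (6.44-fold). Naive and central-memory T genes (median -0.91) and B cell activation genes (median -0.43) were also under the range of random lists, alongside the B cell products noted above.

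Lists inside the range of random lists were CD40 signalling and NF-kB targets (median -0.08, 60.9th percentile), monocyte genes (0.08), chemokines (0.06), interleukin-2 response (0.01), checkpoint genes (-0.06), neutrophil genes (-0.09), adhesion (-0.14, or 0.04 under TMM) and lipid handling (-0.24). Their members went both ways: of 32 CD40 and NF-kB genes, 9 were higher, such as the signalling adaptor Traf1 (2.96-fold), and 5 lower. Of 22 chemokine list genes, 10 were higher and 10 lower, with Ccl5 7.596-fold higher and Ccl3 3.14-fold lower. In lipid handling, Apoe was at 12110 and 2540 CPM, 4.77-fold lower.

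**Figure D3:**
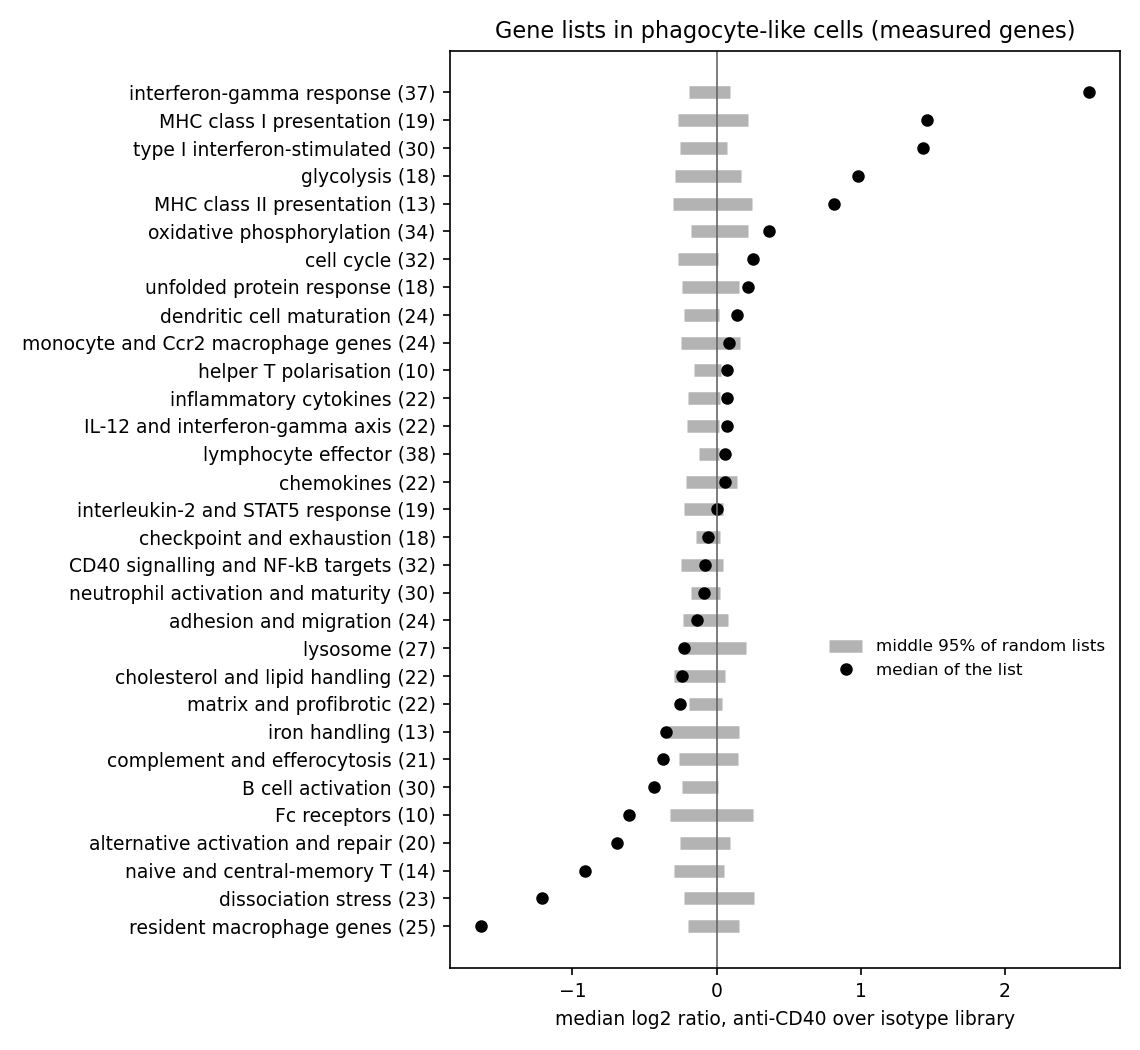
Median log2 ratio of anti-CD40 over isotype (horizontal axis) of the measured genes of each of 31 lists in phagocyte-like cells, as points, with the middle 95% of 10000 matched random lists as grey bars. The interferon-gamma list sat at 2.59 and the resident macrophage list at -1.64.

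Within phagocyte-like cells, resident macrophage-like cells were 634 of 839 (75.6%, 72.5 to 78.4) in the isotype and 975 of 2344 (41.6%, 39.6 to 43.6) in the anti-CD40 library. Different subclusters made up this subset in each library, and several of its marker genes differed between libraries, so its size is given as a value and not as a difference in cell type. Unnamed subclusters held 8.10% and 50.1%, classical monocyte-like cells 10.0% and 2.77%, and nonclassical monocyte-like cells, which patrol vessels, 6.32% and 5.50%. The monocyte-like subsets were split by library too. Classical ones lay in subclusters 5 (81 isotype and 2 anti-CD40 cells) and 6 (3 and 63). Nonclassical ones lay in subclusters 4 (9 and 128) and 7 (44 and 1), so values of these subsets cover both mix and state. Cxcl9 in resident macrophage-like cells was at 0.817 and 1927 CPM. The interferon-gamma list had medians of 2.72 in resident macrophage-like, 2.67 in classical and 3.46 (2.99 with genes at 0 set at their bound) in nonclassical monocyte-like cells, and 2.57 in the unnamed subclusters. The cell cycle list went apart, with medians of 0.33 in resident macrophage-like and 1.29 (bound 1.06) in classical monocyte-like cells, but -1.19 in the unnamed subclusters (27 of 32 lower) and -0.86 over 4 genes in nonclassical monocyte-like cells. The unfolded protein response did so too, with 0.25, 0.13, -0.07 and -0.45. The unnamed set joins subcluster 0, with 34 isotype and 918 anti-CD40 cells, and subcluster 3, with 34 and 257. Subcluster 3 is led by cell cycle genes such as Top2a and Mki67. The cell cycle median of -1.19 thus covers a different mix of these subclusters in each library and does not show lower proliferation within either. Timd4 in resident macrophage-like cells was 1.79-fold higher and Lyve1, a hyaluronan receptor, 1.43-fold lower.

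In cells thinned to 1000 UMIs, Cxcl9 was detected in 0.123% of isotype (1 of 814) and 43.6% of anti-CD40 phagocyte-like cells (1010 of 2315, 41.6 to 45.7), leaving out 25 and 29 shallower cells. Unthinned shares were 0.954% and 75.0%. As background, after thinning, NK cell-like cells had 0 of 133 and 7.58%, and fibroblast-like cells 0 of 35 and 17.9%. Cd40 was in 2.58% (1.60 to 3.92) and 7.90% (6.84 to 9.08), against 13.7% and 47.8% unthinned, with 0% and 0.733% in neutrophil-like and 0% and 3.67% in endothelial-like cells as background. The proliferation gene Mki67 was in 3.19% and 7.30% (7.75% and 24.9% unthinned), Ccr2 in 16.3% and 21.6% (28.4% and 54.7%), and Lyve1 in 16.1% and 7.603% (33.3% and 21.8%). Background shares were 0% and 1.47% for Mki67, 1.47% and 1.83% for Ccr2 and 0% and 1.47% for Lyve1 in neutrophil-like cells. In endothelial-like cells they were 0% and 5.50%, 2.33% and 4.59%, and 6.98% and 7.34%. The anti-CD40 shares of Mki67 and Lyve1 lie near these, but endothelial-like cells also carry phagocyte RNA and so set no clean background. Unthinned, Lyve1 was in 40.4% and 37.4% of resident macrophage-like cells. Il12b was in 0 of 814, which allows a share with a UMI of up to 0.369% by 3 counts and 0.452% by the exact interval, and in 0.389%, not told apart from it. Median depths were 7361 and 10871 UMIs in phagocyte-like, 5239 and 8642.5 in NK cell-like, and 2939 and 2839.5 in neutrophil-like cells.

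Surface tags gave the proteins of some of these genes. Sca-1 was at 11.6 and 153 UMIs per phagocyte-like cell (13.2-fold), the checkpoint ligand PD-L1 at 3.56 and 41.2 (11.6-fold) and the adhesion molecule CD54 at 31.0 and 253 (8.17-fold). CD317 was at 17.0 and 82.0, CD69 at 1.68 and 7.78, and CD11c at 4.95 and 21.9. CD40 was at 8.45 and 32.1 (3.80-fold), and the costimulators CD80 at 2.42 and 7.48 and CD86 at 55.1 and 67.3. CD163 was at 237 and 58.0, Tim-4 at 26.2 and 34.9, and CCR2 at 3.71 and 3.88. The lowest by rank were CD117 (25.8 and 1.34, though on 27.7% and 34.9% of cells), CD55 (38.5 and 2.27), BTLA (7.68 and 1.00) and CD24 (33.8 and 6.14), of which CD55, BTLA and CD24 are also carried by B cells. The highest control tag was at 1.13 and 1.25. Whether the treatment antibody hides or adds to the CD40 tag was not measured.

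**Figure D4:**
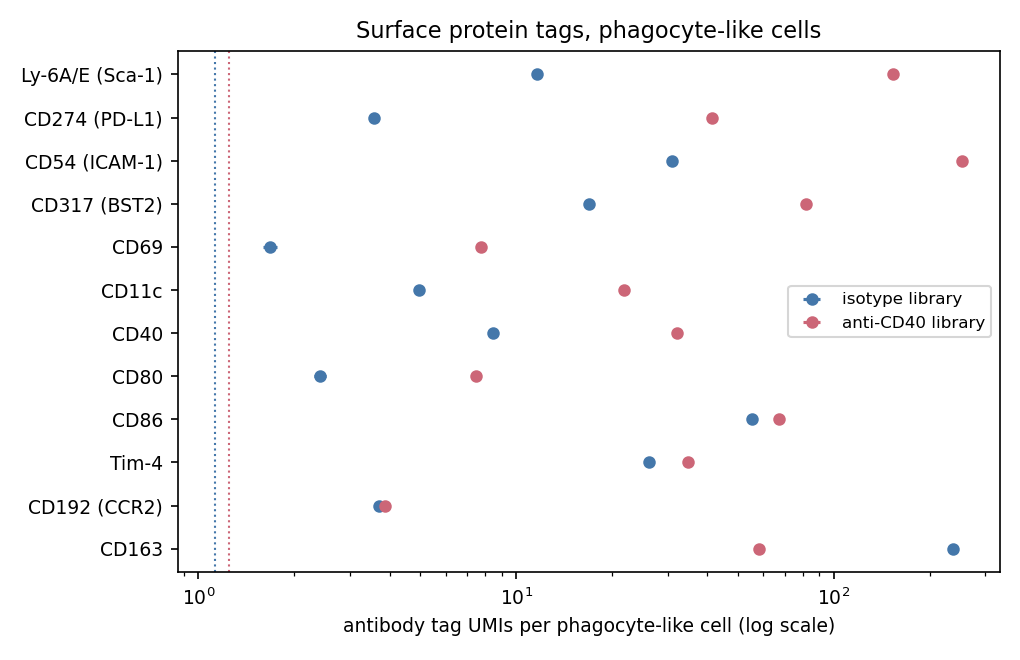
Antibody tag UMIs per phagocyte-like cell (horizontal log axis) for 12 surface proteins in each library, with exact 95% intervals mostly smaller than the points and dotted lines at the highest control tag of each library (1.13 and 1.25). Sca-1 sat at 11.6 and 153, CD163 at 237 and 58.0.

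The comparison within T cell-like cells asked how heart T cells differ after CD40 activation. Genes of cytotoxic and activated T cells were higher in the anti-CD40 library: Gzmb and Gzmk, granule proteases, Ifng, the cytokine that activates macrophages, and the inhibitory receptor genes Pdcd1 and Lag3. Genes of naive and memory cells were lower: Ccr7, which guides cells into lymph nodes, Il7r, a survival receptor, and the transcription factor genes Satb1 and Tcf7. The mix of T cells differed too, with Cd8a at 135 and 675 CPM and Cd4 at 51.1 and 8.47 CPM, so each value covers both mix and state. The class rests on 39 isotype cells (274085 UMIs) and 113 anti-CD40 cells (708405 UMIs), all in cluster 16. When T and NK cell-like cells were clustered again, subcluster 6, led by Ccr7 and Il7r, held 32 isotype and 2 anti-CD40 cells. Subcluster 1, named CD8 T cell-like, held 4 and 107.

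Gzmb (ENSMUSG00000015437) had 0 UMIs in the isotype library and 441 (622.5 CPM) in the anti-CD40 library, at least 56.9-fold higher against 3 counts. Gzmk (ENSMUSG00000042385) had 0 and 209 UMIs, at least 26.95-fold higher. Pdcd1 (ENSMUSG00000026285) had 1 and 90 UMIs, 34.8-fold higher (6.09 to 1390.5). Also at 0 UMIs in the isotype library were Ifitm1 (at least 9.54-fold higher), Lag3 (at least 7.61-fold), Cd38 (at least 6.32-fold) and Pclaf (at least 5.80-fold). Serpina3g was 10.9-fold (6.01 to 22.1), the chemokine gene Ccl4 10.4-fold (5.99 to 19.7) and Ly6a 9.40-fold (6.74 to 13.5) higher. Satb1 was at 459.7 and 33.9 CPM, 13.6-fold lower (8.72 to 21.96). Actn1 was 8.79-fold, Il7r 6.30-fold (4.88 to 8.18) and Tcf7 6.30-fold lower. Ifng (ENSMUSG00000055170) was at 36.5 and 322 CPM, 8.82-fold higher (4.71 to 18.6). Il12rb1 had 2 and 33 UMIs, 6.38-fold higher (1.63 to 54.9). Cd40lg, the ligand of CD40 on helper T cells, had 16 and 4 UMIs, 10.3-fold lower (3.34 to 42.5). Cxcl10 was 1.73-fold higher (1.01 to 3.12) and Ifngr1 1.33-fold higher (1.06 to 1.69), while Cxcl9 had 0 and 35 UMIs, below the 102 CPM that free RNA from phagocytes would bring. Cd40 had 0 and 8 UMIs, Ifngr2 4 and 3, Il12rb2 0 and 4, Il12b 0 and 1, and Il12a was listed at 0 in both libraries.

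In thinned cells Gzmb was detected in 0 of 39 isotype T cell-like cells, which allows a share with a UMI of up to 7.69% by 3 counts and 9.03% by the exact interval, and in 46 of 112 (41.1%, 31.9 to 50.8) in the anti-CD40 library, leaving out 0 and 1 cells. The unthinned shares were 0% and 72.6%. Phagocyte-like cells, as background, had 0% and 0.389%. Ifng was in 5.13% and 15.2% (15.4% and 54.0% unthinned), with 0.123% and 0.216% in phagocyte-like cells. The median depth of T cell-like cells was 6114 and 6066 UMIs. When the mixed cluster of T cell and phagocyte markers was counted as T cells, the log2 ratio of Gzmb was 4.74 instead of 5.98, of Gzmk 3.51 instead of 4.93, of Pdcd1 2.15 instead of 3.33 and of Ifngr1 -0.41 instead of 0.40. Il7r was then at -4.14 instead of -2.56, Pclaf at 4.27 instead of 2.88, and Cxcl9 and Cxcl10, abundant in phagocytes, at 6.30 and 2.996. Ccl4 was at 1.65 instead of 3.13 with a filter of 500 genes and 5% mitochondrial UMIs, where the class had 19 and 182 cells, and Ifng at 1.75 instead of 2.84 after thinning.

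**Figure D5:**
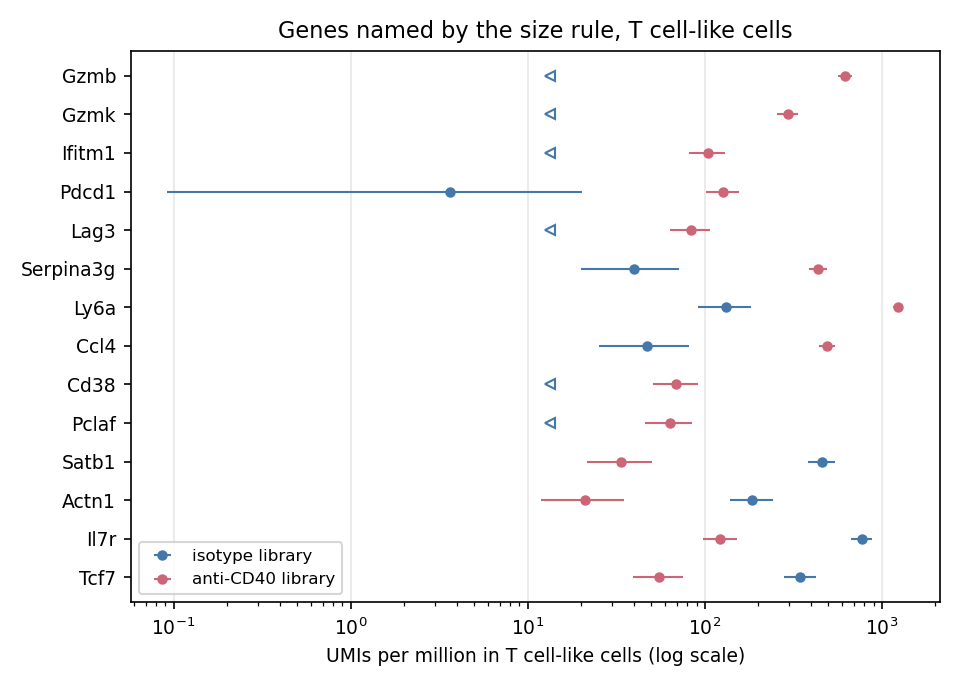
Class CPM (horizontal log axis) of 14 genes named by size in T cell-like cells, as points for each library with exact 95% Poisson intervals. Open triangles stand at the upper limit of genes with 0 UMIs, and Satb1 sat at 459.7 and 33.9 CPM.

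Of the lists in T cell-like cells, naive and central-memory genes had 16 of 17 lower (median log2 ratio -2.44), with Ccr7 41.4-fold lower. Lymphocyte effector genes had 26 of 38 higher (median 0.99), such as the transcription factor gene Tbx21 (2.82-fold) and Ccl5 (4.90-fold), while Xcl1 was 5.54-fold lower. Cell cycle genes had 21 of 23 higher (median 1.27, or 0.97 with genes at their bound) and glycolysis 12 of 16 (median 1.26), with Tpi1 5.59-fold higher. The interferon-gamma response had 27 of 31 higher (median 1.16), MHC class I 15 of 19 (1.03), checkpoint genes 13 of 18 (0.79, bound 0.68), oxidative phosphorylation 14 of 34 (0.51) and type I interferon genes 15 of 26 (0.50). With free RNA subtracted the interferon-gamma, MHC class I and type I medians were 0.99, 0.96 and 0.32. MHC class II genes had a median of 1.49, which was 0 with free RNA subtracted, and 1 of their 10 genes exceeded the free RNA level more than 2-fold. As subtracted values below 0 were set to 0, that median does not show that class II was alike in the 2 libraries. Chemokines (0.71, bound 0.57), monocyte genes (0.95, bound 0.75), complement (0.76), dendritic cell maturation (0.82), neutrophil genes (0.53) and lysosome (0.49) also stood above random lists, in cells where free phagocyte RNA was 3.97% and 6.86% of the phagocyte level. Inside the range of random lists, helper T polarisation had a median of 0.78 (bound 0.36), the interleukin-12 and interferon-gamma axis 0.48, unfolded protein response 0.43, adhesion 0.36, iron 0.31, interleukin-2 response 0.23, Fc receptors 0.17, lipid handling 0.13, inflammatory cytokines 0.03, CD40 and NF-kB targets -0.06 and matrix -0.13. Resident macrophage genes (-0.98), dissociation stress genes (-0.63), alternative activation (-0.62, but 1.14 after thinning) and B cell activation (-0.33) were under it. Thinning also moved chemokines to 2.68, neutrophil genes to 2.64, dendritic cell maturation to 2.09, matrix to 1.07 and Fc receptors to -0.72, and with no count minimum helper T polarisation was at -0.08.

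NK cell-like cells, compared for the same question, had higher interferon-inducible genes, cell cycle genes and glycolysis genes in the anti-CD40 library. In the second clustering of T and NK cell-like cells, subcluster 0, whose leading genes include Klra8, Pde2a and Arl4d, held 110 isotype and 6 anti-CD40 cells. Subcluster 2, with Gzmb and Mki67 among its leading genes, held 4 and 55, and subcluster 4, with Prf1 and Gzma, 4 and 51. Values of the NK cell-like class thus cover both mix and state. Ly6a had 2 and 2068 UMIs, at 2.42 and 897 CPM, 371-fold higher (102.5 to 3063). Ifng, which NK cells make as T cells do, was at 294 and 263 CPM, a ratio of 0.894 (0.769 to 1.04). Phagocyte RNA was 13.4% and 27.2% of the phagocyte level in this class, and 1.47% and 3.06% without a phagocyte-marked subcluster of 9 and 45 cells, left out in an alternative chosen after seeing the data. Most of it thus lay in these cells and was not free RNA spread over the class. Log2 ratios without it are given where they differ most.

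Iigp1 had 3 and 776 UMIs, 92.7-fold higher (31.6 to 451), and Ccl7 was at 4.84 and 168 CPM, 34.8-fold higher (13.5 to 128). Cxcl9 had 0 and 520 UMIs, at least 62.15-fold higher, at 0.555 of the level this phagocyte RNA would bring. Gbp2b had 0 and 293 UMIs, at least 35.0-fold higher. Without the subcluster the log2 ratio was 5.57 for Ly6a (6.19 with it), 3.01 for Iigp1 (4.67), 2.83 for Cxcl9 (4.56), 1.32 for Gbp2b (3.78) and 1.51 for Ccl7 (3.59). Pde2a, a phosphodiesterase, was 11.2-fold (7.20 to 17.9) and Arl4d, a small GTPase, 9.70-fold (6.95 to 13.8) lower. Ccl24 had 34 and 0 UMIs, at least 31.6-fold lower, with a log2 ratio of -2.35, or -0.53 without the subcluster. Cxcl10 was 6.15-fold higher (4.20 to 9.35), at 0.955 of the phagocyte RNA level, with 0 and 88 UMIs without the subcluster. Il12rb1 was 3.09-fold (1.73 to 5.98) and Ifngr2 2.06-fold higher, the latter with a log2 ratio of 0.03 without the subcluster. Ifngr1 was at 644 and 317 CPM, 2.03-fold lower. With a filter of 500 genes and 5% mitochondrial UMIs, where the class had 107 and 49 cells and most of these ratios were lower too, the log2 ratio of Iigp1 was 2.64. Il12rb2, the inducible interleukin-12 receptor chain, was at 70.2 and 29.9 CPM, 2.34-fold lower (1.62 to 3.37), but its log2 ratio of -1.01 became 0.11 with that filter. Cd40 had 0 and 47 UMIs, 0.830 of the phagocyte RNA level, Cd40lg had 0 and 2, and Il12a and Il12b were listed at 0 in both libraries.

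The interferon-gamma list in NK cell-like cells had 34 of 35 genes higher (median 1.68, bound 1.51), which was 0.53 with phagocyte RNA subtracted and 1.17 without the subcluster. Type I interferon genes had 28 of 30 higher (1.38, bound 1.33), MHC class I 11 of 19 (0.64), glycolysis 11 of 18 (0.81) and the cell cycle 27 of 32 (1.04, bound 0.92), with Mki67 15.2-fold and Gapdh 3.09-fold higher. With phagocyte RNA subtracted the type I interferon median was 0.73 and that of MHC class I 0.32, and without the subcluster they were 0.94 and 0.61. MHC class II genes had a median of 1.03 that turned to -1.03 with phagocyte RNA subtracted. Also above random lists were chemokines (0.97, bound 0.80), monocyte genes (0.90, bound 0.75), inflammatory cytokines (0.57, bound 0.39), lysosome (0.53), iron (0.41), dendritic cell maturation (0.38), lipid handling (0.32), matrix (0.31), the unfolded protein response (0.30), oxidative phosphorylation, neutrophil genes and complement (each 0.26), interleukin-2 response (0.23) and CD40 and NF-kB targets (0.13). Naive T genes (-1.39), resident macrophage genes (-0.67), B cell activation (-0.40) and dissociation stress genes (-0.36) were under them, with lower members such as Bach2 (12.3-fold) and Satb1 (5.10-fold). Lymphocyte effector genes had a median of -0.17 (3.68th percentile), or 0.05 without the subcluster, with the transcription factor gene Eomes 3.59-fold lower. Other medians inside the range were 0.05 for the interleukin-12 axis, -0.09 for checkpoint, -0.10 for helper T, -0.11 for Fc receptor (0.04 under TMM), -0.15 for alternative activation and -0.27 for adhesion genes. Thinning moved complement to 2.21, matrix to 1.65, inflammatory cytokines to 1.496 and lipid handling to -0.28. Scaling by TMM or the median of ratios raised log2 ratios of the class by a median of 0.10 or 0.11.

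Neutrophil-like cells, again compared for differences after CD40 activation, had the highest interferon-gamma list median of the 5 classes. Gbp2 was far higher, as was Ifi47, an interferon-inducible GTPase gene, and Ccl3, a chemokine gene of activated myeloid cells, was lower. Different clusters made up the class: 163 of 167 isotype cells were in cluster 12, led by Slc7a11, Slpi, Ptgs2 and Il1b, and 274 of 304 anti-CD40 cells in cluster 8, led by Ngp, Retnlg and Lcn2, granule genes of younger neutrophils. Monocyte genes differed within it as well, with Plac8 45.2-fold and Ly6c2 18.0-fold higher in the anti-CD40 library.

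Gbp2 (ENSMUSG00000028270) was at 19.1 and 3897 CPM, 204-fold higher (107 to 446). Ifi47 was 114-fold (48.8 to 353) and Upp1, uridine phosphorylase, 78.1-fold (42.4 to 163) higher. Gbp4 had 1 and 575 UMIs, 288-fold higher with a wide interval (51.5 to 11390), and Gbp5 1 and 406 UMIs, 203-fold higher (36.3 to 8048). Tpcn1 was 15.98-fold (5.67 to 62.2), Slc38a1 8.99-fold (4.47 to 20.0) and Ccl3 8.20-fold (6.97 to 9.68) lower. Cxcl10 was 33.1-fold higher (18.4 to 66.7). Cxcl9 had 0 and 154 UMIs, at least 25.7-fold higher and 1.43 times the free RNA level. Ifngr1 (1.11-fold lower, 0.781 to 1.58) and Ifngr2 (1.01-fold lower, 0.722 to 1.39) did not differ detectably at this depth, and both turned slightly higher under TMM and the median of ratios. Counting the mixed phagocyte and neutrophil clusters in the class lowered the log2 ratio of Gbp2 from 7.07 to 5.74 and of Ifi47 from 5.89 to 4.49, and moved Ccl3 from -2.97 to -1.95. Cd40 had 3 and 7 UMIs, Ifng 2 and 1, Il12rb1 0 and 8, Il12a 1 and 2, Il12b 0 and 2, and Cd40lg and Il12rb2 were listed at 0 in both libraries.

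All 34 interferon-gamma genes (median 3.35), 29 type I interferon genes (2.66) and 19 MHC class I genes (2.25) were over 1.5-fold higher in neutrophil-like cells of the anti-CD40 library, such as Ifit2 (2 and 359 UMIs, 89.9-fold, 24.7 to 745), Zbp1 (33.8-fold) and H2-Q7 (24.9-fold). With free RNA subtracted these medians were 3.22, 2.70 and 2.22. MHC class II genes had a median of 0.93, which was -1.26 with free RNA subtracted. Also above random lists were monocyte genes (1.00), chemokines (0.99), lymphocyte effector genes (0.31), the interleukin-12 axis (0.19), complement (0.18), glycolysis (0.17) and B cell activation (0.07). Neutrophil activation and maturity genes had 13 of 27 higher (median 0.28), with the granule genes Camp 16.5-fold and Lcn2 4.07-fold higher, and Ptgs2 4.78-fold lower. CD40 and NF-kB targets stood above random lists with a median of 0.04, as the all-gene median was -0.30. Resident macrophage genes (-1.01), alternative activation genes (-1.01, with Thbs1 10.4-fold lower) and dissociation stress genes (-0.50) were lower. Inside the random range were cell cycle (0.25), interleukin-2 response (0.20), dendritic cell maturation (0.08), Fc receptors (-0.02), lysosome (-0.11), lipid handling (-0.12), iron (-0.24), inflammatory cytokines (-0.28), adhesion (-0.29), matrix (-0.43), naive T (-0.51), checkpoint (-0.55) and helper T genes (-0.94). Oxidative phosphorylation (-0.29) and the unfolded protein response (-0.25) were inside it too. These, and the adhesion, inflammatory cytokine, iron, lysosome and lipid lists, turned above 0 under TMM and the median of ratios, which raised log2 ratios of the class by a median of 0.30 and 0.31. Free phagocyte RNA in the class was 4.34% and 7.65% of the phagocyte level.

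Endothelial-like cells, the lining of vessels, were compared through lists and the CD40 and interferon genes only. Cxcl9 was at 42.8 and 2893 CPM, 67.5-fold higher in the anti-CD40 library (40.2 to 124) and 3.62 times the level free RNA would bring. Free RNA was 26.2% and 53.5% of the phagocyte level, the highest of the classes compared. Cxcl10 had 0 and 590 UMIs, at least 54.9-fold higher and 1.18 times the free RNA level. Cd40 had 2 and 47 UMIs, 6.56-fold higher (1.72 to 55.8) but at 1.11 and 0.831 times the free RNA level. Ifngr1 was 1.37-fold lower (1.06 to 1.76) but higher after thinning (log2 ratio 1.18), and Ifngr2 was 1.18-fold higher (0.741 to 1.94). Ifng had 0 and 7 UMIs, Il12rb1 0 and 10, Il12b 0 and 1, Il12a and Il12rb2 1 and 0 each, and Cd40lg was listed at 0 in both libraries.

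In endothelial-like cells 37 of 38 interferon-gamma genes were over 1.5-fold higher (median 3.18, bound 3.05), and 26 of the 38 exceeded the free RNA level more than 2-fold. Type I interferon genes had 28 of 29 higher (1.67, bound 1.65), for example Zbp1 (1 and 295 UMIs, 82.4-fold, 14.7 to 3264), and MHC class I 19 of 19 (1.77), for example Tap1 (13.5-fold). With free RNA subtracted these medians were 2.67, 1.35 and 1.33. MHC class II genes had a median of 1.80, which was 0 with free RNA subtracted, and 0 of 12 exceeded the free RNA level more than 2-fold. Neither value can decide on class II in these cells. Subtracted values below 0 were set to 0, and at this free RNA level a gene would have had to exceed its phagocyte level to pass. CD40 and NF-kB targets had 17 of 29 higher and 0 lower (0.55), with Traf1 5.68-fold higher (1.85 to 28.3). Chemokines had 14 of 18 higher (1.06), while Cxcl12, which retains leukocytes and progenitors, was 4.14-fold lower. Adhesion genes had a median of 0.74 (bound 0.52), with Vcam1, which leukocytes bind on vessel walls, 4.16-fold higher, and dendritic cell maturation genes 0.91, with the PD-L1 gene Cd274 15.4-fold higher. Also above random lists were monocyte genes (1.55, bound 1.52), lymphocyte effector genes (0.99, bound 0.81), cell cycle (0.96, bound 0.50), inflammatory cytokines (0.93, bound 0.78), neutrophil genes (0.84), glycolysis (0.79), the interleukin-12 axis (0.79, bound 0.52), the unfolded protein response (0.52), Fc receptors (0.42), matrix (0.41) and lysosome (0.28). Naive T genes (-0.89) and resident macrophage genes (-0.52, but 0.28 after thinning) were under them. Inside the range were interleukin-2 response (0.24), alternative activation (0.23, bound 0.17), complement (0.04), lipid handling (0.0047), oxidative phosphorylation (0.0027), B cell activation (-0.10), iron (-0.21), checkpoint (-0.21, bound -0.30) and dissociation stress genes (-0.27). The helper T list had 1 measured gene.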

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

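CD41, the platelet integrin chain, is not part of any comparison. In a reading made after the data were seen, its mean tag level stood far above the control tags in unnamed cluster 5 of the anti-CD40 library. It was at 209.3 UMIs per cell (206.6 to 212.1) over 108 cells, against a highest control tag of 0.407, and at 0.695 over 249 isotype cells of the same cluster. Cells with at least 100 CD41 UMIs numbered 5 (4.63%, 1.52 to 10.5). As every other cell had under 100, most of the 22607 CD41 UMIs lay in these few cells. The interval of the mean counts UMIs and does not cover this spread between cells. Endothelial-like cells had such cells too, 3 of 54 (5.56%) in the isotype and 3 of 125 (2.40%) in the anti-CD40 library, with means of 33.6 and 16.2.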

How the results depend on the processing

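The 28 alternatives fixed in advance and the 7 chosen after seeing the data (called added) changed 1 choice at a time, apart from the cell filters, in which the gene minimum and the mitochondrial limit changed together; with 1 library per group no replicate could be left out. A value counts as reversed where its interval excludes 0 in the main setting and the alternative has the other sign; a value whose interval includes 0 can change sign and is then counted as stayed or moved. Of 1006 list medians, 923 stayed within their intervals, 76 moved and 7 reversed; of 897 values of named genes 592 stayed, 304 moved and 1 reversed; of 24 transcript shares 6 stayed and 18 moved. Differences in share, anti-CD40 minus isotype, were 21.99 points for phagocyte-like, -15.1 for B cell-like, 1.12 for T cell-like, 0.578 for neutrophil-like, -0.610 for NK cell-like, 1.18 for mature dendritic cell-like and -2.32 for conventional dendritic cell-like cells. At 500 genes and 5% mitochondrial UMIs phagocytes were at 16.9, T cells at 5.66 and NK cells at -5.87 points, and Il12rb2 in NK cells reversed from a log2 ratio of -1.01 to 0.11. Over every barcode phagocytes were at 28.4, B cells at -27.1, T cells at 2.99 and neutrophils at -1.32. With mixed clusters put into their best class B cells were at -28.1 and T cells at 6.56. At a Leiden resolution of 0.5 phagocytes were at 27.9, T cells at 5.37 and neutrophils at -4.80. At 2.0 phagocytes were at 14.9, B cells at -22.0, T cells at 3.24, NK cells at -3.05 and conventional dendritic cells, reversed, at 3.40. With response genes kept B cells were at -24.1 and T cells at 5.94. With 15 components phagocytes were at 15.1, T cells at 3.45 and conventional dendritic cells, reversed, at 1.24. With each cell placed by its largest marker share phagocytes reversed to -2.39 and conventional dendritic cells to 10.6. T cells were then at 4.76, neutrophils at 3.63 and mature dendritic cells at 5.61. Each share was divided by its mean over all kept cells, which works against abundant classes by construction. Phagocyte-like cells were then 12.9% and 10.5%. At 25% mitochondrial UMIs (added) B cells were at -24.6, T cells at 5.99 and neutrophils at -2.08, and over named classes alone (added), where the total is smaller, B cells were at -21.9 and T cells at 1.25. A subcluster resolution of 1.5 moved the resident macrophage-like share among phagocytes from -33.97 to -53.5 points. The mature dendritic cell class gave no value at either resolution or with 15 components. The interferon-gamma median with a prior of 1 CPM was 3.23 in phagocytes and 2.12 in NK cells, which a smaller prior does by construction. With phagocyte RNA subtracted (added) it was 0.53 in NK cells, where MHC class II reversed from 1.03 to -1.03. Thinning raised the interferon-gamma median of T cells to 1.51 and reversed alternative activation in T cells (1.14) and resident macrophage genes in endothelial-like cells (0.28). TMM and the median of ratios, which multiply all genes of a class by 1 factor, reversed oxidative phosphorylation (0.096 and 0.10) and the unfolded protein response (0.063 and 0.070) in neutrophils. Where no construction is named, the cause was not tested. Depth limits the T cell-like class most, where 3 counts equal 10.9 CPM in the isotype library.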

Other observations

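The sum of B cell genes over all barcodes is a test set up before its result was seen. The B cell share over every barcode and the thinning of cells were alternatives fixed in advance, but their use as tests, like every other test reported here, was chosen after the result was seen. The classes too small for the comparisons also differed in interferon genes. Conventional dendritic cell-like cells (88 and 48 cells), which take up antigen and prime T cells, had Cxcl9 at 4.78 and 632 CPM, 2.77 times the free RNA level in the anti-CD40 library. Fibroblast-like cells (49 and 67 cells), which make the matrix, had Ly6a at 640.1 and 3592 CPM, Gbp2 at 21.4 and 1259 CPM and Iigp1 at 10.7 and 1550.5 CPM. These were 7.72, 6.75 and 5.43 times the free RNA level in the anti-CD40 library, whereas Cxcl9 in fibroblast-like cells was at 0.773 of it. Mature dendritic cell-like cells, 54 in the anti-CD40 library and 2 in the isotype library, had Cd40 at 437 CPM (317 UMIs), Cxcl9 at 4455 CPM and Il12b at 110.3 CPM (80 UMIs) in the anti-CD40 library; the 2 isotype cells had Cd40 and Il12b at 474.7 CPM each (18 UMIs) and no Cxcl9.

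Surface proteins, chosen after their values were seen, differed in other classes too. On T cell-like cells the checkpoint receptor PD-1 was at 0.846 and 6.96 tag UMIs per cell, CD4 at 27.7 and 3.81 and CD8a at 27.0 and 38.2. On endothelial-like cells PD-L1 was at 21.9 and 465 and CD54 at 242 and 708. On neutrophil-like cells PD-L1 was at 1.19 and 22.7. On the 15 B cell-like cells of the anti-CD40 library CD44, an adhesion receptor that is higher on activated lymphocytes, was at 522, against 10.9 on the 395 isotype cells, and CD86 at 65.3 against 4.50. These means over 15 cells carry no spread between cells. Cxcl9 was detected in 6 of the 15 (40%), and CD86 was at 67.3 on phagocyte-like cells of that library. Phagocyte material can thus be part of these values, which was not tested.

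B cell-like cells had a far lower share in the anti-CD40 library. Over every deposited barcode the share was 57.6-fold lower (41.0 to 83.5), which argues against loss in the filters. Cd79a, Cd79b and Ms4a1, summed over all barcodes whatever their cluster, were 27.4-fold lower (26.3 to 28.6), which argues against B cells placed in other clusters. Against fibroblast-like cells, the smallest of 3 such ratios, B cell-like cells were 36.0-fold fewer (21.6 to 64.9), against dilution by phagocytes alone. Treatment stays a candidate explanation, and a difference in perfusion, digestion or sorting between the 2 preparations was not tested and cannot be separated from it.

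The interferon-gamma response list was higher in phagocyte-like cells. With every cell thinned to 1000 UMIs its median log2 ratio was 2.74 (2.39 to 3.23). This could not decide on depth as a cause. CPM already divides out depth, and thinning leaves the expected share of each gene in a cell unchanged. Within the clusters with at least 50 cells of each library, made without these genes, the list median was 1.78 (1.57 to 1.98) in cluster 2, 3.31 in cluster 13 and 2.75 in cluster 17. These held 73, 127 and 68 of the 2344 anti-CD40 phagocyte-like cells. Clusters 0 and 1, with 940 and 895 of them but 39 and 8 isotype cells, were not compared. For the cells compared, the medians argue against another mix of clusters as the whole cause, though not against a finer mix within a cluster. They were not corrected for free RNA from other phagocyte-like cells, which can be part of the smallest one. In cluster 2, Cxcl9 was at 0.846 and 107 CPM, against 1927 CPM in resident macrophage-like cells of the anti-CD40 library. Type I interferon-stimulated genes were higher too (28 of 30, median 1.43), so the lists do not tell which interferon acted. Treatment stays a candidate explanation, and other differences between the preparations were not tested and cannot be separated from it.

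The cluster with T cell and phagocyte genes held cells of the anti-CD40 library alone, with Cd8b1 at 270.1, C1qa at 3771, Ifng at 209.2 and Mki67 at 356 CPM. Its median of 16851 UMIs was 99.5% of the sum of the T cell-like and phagocyte-like medians, as a T cell and a phagocyte in 1 droplet would give. Cycling phagocyte-like cells (cluster 9) were as deep, however, at 16867. The highest control tag was at 45.1 UMIs per cell in the mixed cluster, against 1.25 in phagocyte-like and 0.301 in T cell-like cells of the library. A simple pair of such cells would not carry that much. This mean can rest on few cells, and its cause was not tested. Of the library's T cell-like cells, this cluster included, 49.7% (44.3 to 55.1) had a share of C1qa, C1qb and C1qc UMIs of at least 20% of the phagocyte-like median. So did 43.4% (39.1 to 47.8) of neutrophil-like cells with their mixed clusters, 38.4% (29.8 to 47.5) of endothelial-like, 17.9% (9.61 to 29.2) of fibroblast-like and 17.7% (12.6 to 23.7) of NK cell-like cells. In the isotype library 1 of 39 T cell-like cells, 4.48% of NK cell-like, 38.1% of neutrophil-like and 42.2% of B cell-like cells did, the last 2 with their mixed clusters. The T cell share exceeded those of NK cells and fibroblasts but not, beyond counting error, those of neutrophils and endothelial cells. Counted by cluster instead, 67.3% (62.1 to 72.3) of T cell-like cells were in this cluster, against 41.3% (37.0 to 45.7) of neutrophil-like cells in mixed clusters, and 22.7% of NK cell-like cells were in a phagocyte-marked subcluster. The measures disagree for neutrophils, and the clustering decides which cells each counts. Chance capture in 1 droplet and binding of T cells to phagocytes, in the tissue or after digestion, cannot be told apart with these values.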
